A study of Homo sapiens with 19 samples.

How the data were processed

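Gene expression was measured on Affymetrix arrays in 9 human cell types. They were GM12878 (an Epstein-Barr virus transformed B lymphoblastoid line), K562 (an erythroleukemia line), HepG2 (a liver cancer line), H1 (embryonic stem cells), HUVEC (umbilical vein endothelial cells), HMEC (mammary epithelial cells), NHEK (epidermal keratinocytes), HSMM (skeletal muscle myoblasts) and NHLF (lung fibroblasts). The main table held 17 arrays of 8 cell types, 3 of K562 and 2 of each other type. H1 had 2 arrays on another array design, in a table of its own. The series describes cultures in duplicate, but K562 had 3 arrays, and no label tied an array to a culture, donor or passage. P-values therefore measured only the spread between these arrays, which may be technical.

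The deposited values were RMA intensity summaries per probe set on a linear scale, with RMA taken from the submitters' processing notes. The software version, probe set definition and RMA settings were not given in the sources used here. Each table was normalized separately and held no detection calls. The number of arrays limits the precision of each value. Log2 was taken of the deposited values and no further normalization was applied. In the main table the median intensity was 13.5 (log2 3.76) and the lower quartile was log2 2.98, so differences against a type without the transcript were compressed by this floor.

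The main table had 22277 probe sets, of which 62 were controls, 19724 were assigned to 1 gene, 568 to several genes, and 1923 had no gene name in the annotation used here. After removal of 40 probe sets of XIST, TSIX and Y-linked genes, 19684 probe sets of 12136 genes were tested. For the 4496 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene. The H1 table had 54675 probe sets, 22215 of them shared with the main table. Probe sets of several genes, unnamed probe sets and genes only in the H1 table were not used here.

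Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per cell type, with 1 spread per gene shared by the types). A gene was called higher (or lower) in a type than in every other type when the largest of its 7 one-sided p-values, adjusted with Benjamini-Hochberg over the 12136 genes, was under 0.05 and the type lay at least 2-fold beyond the nearest other type. The margin is the log2 distance to that nearest type. NHEK was set against HMEC, NHLF against HSMM and K562 against GM12878, and the mean of HMEC and NHEK against the mean of HSMM and NHLF, two-sided, with the same thresholds. In the last of these the arrays were the replicates. The established lines in the main table (GM12878, HepG2 and K562) were set against the 5 finite-lifespan cultures with 1 mean per cell type as the replicate. The groupings as established or finite-lifespan and as epithelial or mesenchymal are textbook knowledge and not in the labels. Agreement of replicates was tested with a one-sided permutation test (100000 permutations of the cell type labels) on the mean squared log2 difference between arrays. H1 could not be tested against the other types, as it was alone on its platform. Its genes were ranked within each array among the shared probe sets, and the percentiles were set beside those of the other types without a test.

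The 25 gene lists, written from textbook knowledge, were B lymphocyte, NF-kappaB targets in lymphocytes, T lymphocyte, monocyte and macrophage, erythroid and megakaryocyte, hepatocyte, cholesterol synthesis and uptake, basal keratinocyte, keratinocyte differentiation, luminal and simple epithelial, epithelial junction and splicing, skeletal myoblast and muscle, fibroblast and extracellular matrix, lung mesenchyme regulators, HOX cluster, endothelial, pluripotency, cell cycle, p53 targets and cell cycle inhibitors, cancer-testis, MHC class I presentation, MHC class II presentation, interferon response, glycolysis and hypoxia, and cytosolic ribosomal proteins. Each was tested in each type against the mean of the other 7 types (200 tests) and in each comparison (125 tests) with limma's camera at a preset correlation of 0.01, adjusted within each family, and again with an estimated correlation and with fry. Fry's p asks whether the genes move one way, not whether they differ from other genes. List members were counted as higher or lower at an adjusted p under 0.05 at any fold, over all genes and also adjusted over the list alone. Of 130 list calls by type 62 held with an estimated correlation, and of 42 between groups 22 held. List calls in the text held in both ways unless an adjusted p with an estimated correlation is printed beside them.

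Genes were named by rule. Per type these were the 10 called genes with the largest margin above the next type, the 5 with the largest margin below it, and up to 4 examples per fitting list with the largest difference from the mean of the other types. Per comparison these were the 10 with the largest difference on each side, and for H1 the 15 with the largest percentile gap and the 5 lowest. Other members of the lists were picked as examples after their values were seen. Among the 5 genes lowest in HSMM, 1 is not reported here. The comparisons, lists, naming rule, thresholds and alternatives were chosen before the data were examined, except where the text says otherwise.

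The tests were tried on simulated data of 12136 genes, with 67, 67 and 66 genes changed by 2-fold, 4-fold and 8-fold. For genes higher in HMEC 4.5%, 97% and 97% were recovered, and for K562 14.9%, 98.5% and 98.5%. For NHEK against HMEC 43.3%, 97% and 95.5% were recovered, with 3 of 11936 unchanged genes called. For HMEC and NHEK against HSMM and NHLF 56.7%, 100% and 100% were recovered. For the established lines 13.4%, 55.2% and 75.8% were recovered, with 3 unchanged genes called. In the other settings no unchanged gene was called. Unchanged genes had the same simulated mean in every type, which makes false calls against every other type rare by design. Genes high in similar types, such as HMEC and NHEK together, were not tried as a source of such calls. All 5 shifted lists and 0 of 25 unchanged lists were called by camera. Genes changed by 2-fold lay on the fold threshold itself, and the simulated genes varied independently, so the list result does not cover correlated genes.

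The alternatives were the mean of all probe sets of a gene, the probe set with the largest variance, removal of dim genes, quantile normalization, median centring, eBayes with trend and robust settings, the replicate number as a block, at least 4-fold, leaving out each array or each cell type, and arrays as replicates for the established lines. Leaving out 4 arrays at once was added after the data were seen. RNA quality was read as the log2 difference between the 3' and 5' control probe sets of ACTB and GAPDH. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.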

Results

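Each cell type expressed the genes of its lineage, and arrays of the same type were far closer to each other than to those of any other type. Over 12136 genes, the mean squared log2 difference was 0.137 between arrays of a type (10 pairs) and 1.93 between arrays of different types (126 pairs), a ratio of 14.1 (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The widest pair within a type was HepG2 at 0.302, and the closest pair of different types was an HMEC and an NHEK array at 0.337. Between replicates, 7.39% of genes differed over 2-fold in HepG2, 5.53% in NHLF, 2.94% in HSMM, 1.94% in GM12878, 1.10% in HMEC, 0.297% in NHEK and 0.115% in HUVEC. Of the 3 K562 arrays, replicates 1 and 2 differed over 2-fold at 0.0082% of genes and replicate 0 differed from them at 1.43% and 1.38%.

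**Figure D1:**
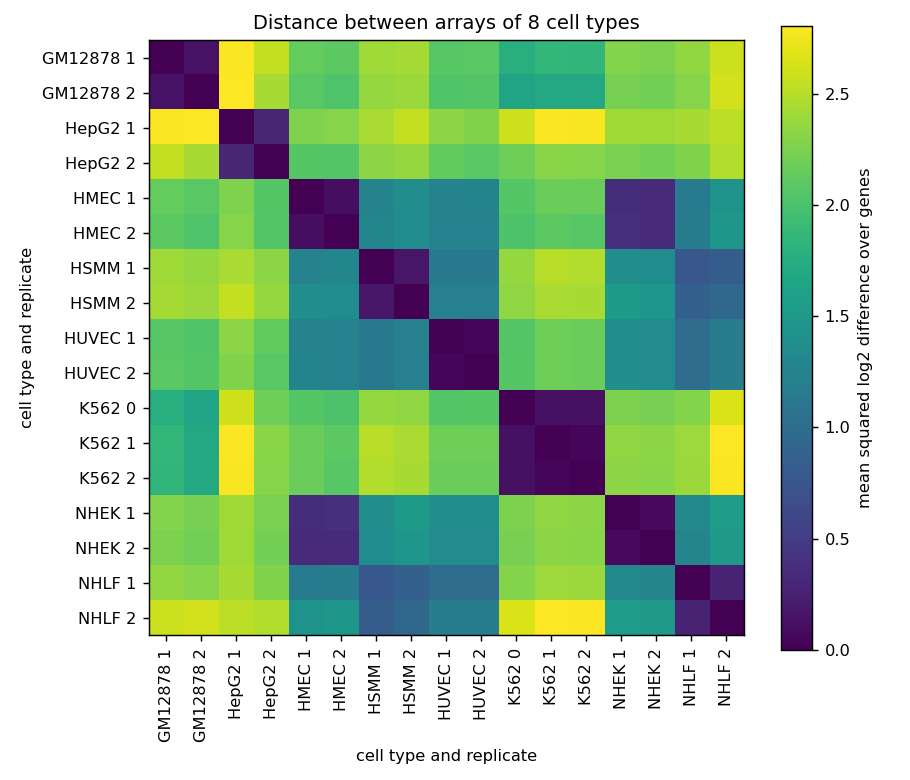
Mean squared log2 difference over 12136 genes between each pair of 17 arrays, with cell type and replicate on both axes and color from 0 up. Arrays of a type form dark blocks on the diagonal (0.302 at most), and HMEC and NHEK lie closest among the different types (0.337).

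The 3' minus 5' signal of ACTB, read as a measure of RNA quality where a higher value is poorer, differed between the types. It was highest in HepG2 at log2 2.99 ± 0.53 (SD, n = 2), then 1.63 ± 0.10 in K562 (SD, n = 3), and 1.24 ± 0.23 in NHEK, 1.05 ± 0.04 in HUVEC, 1.04 ± 0.21 in HMEC, 0.96 ± 0.05 in NHLF, 0.88 ± 0.19 in H1, 0.62 ± 0.08 in GM12878 and 0.60 ± 0.19 in HSMM (SD, n = 2 each). The same measure for GAPDH lay between -0.17 and 0.38 in every type.

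In all, 1878 genes (15.5% of those tested) were higher in 1 type than in every other and 530 were lower in 1 type than in every other. The 3 established lines held most of them, with 518 higher and 198 lower genes in HepG2, 452 and 180 in K562, and 366 and 127 in GM12878. HUVEC had 163 higher and 5 lower genes, HSMM 149 and 12, NHLF 141 and 3, NHEK 68 and 1, and HMEC 21 and 4.

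**Figure D2:**
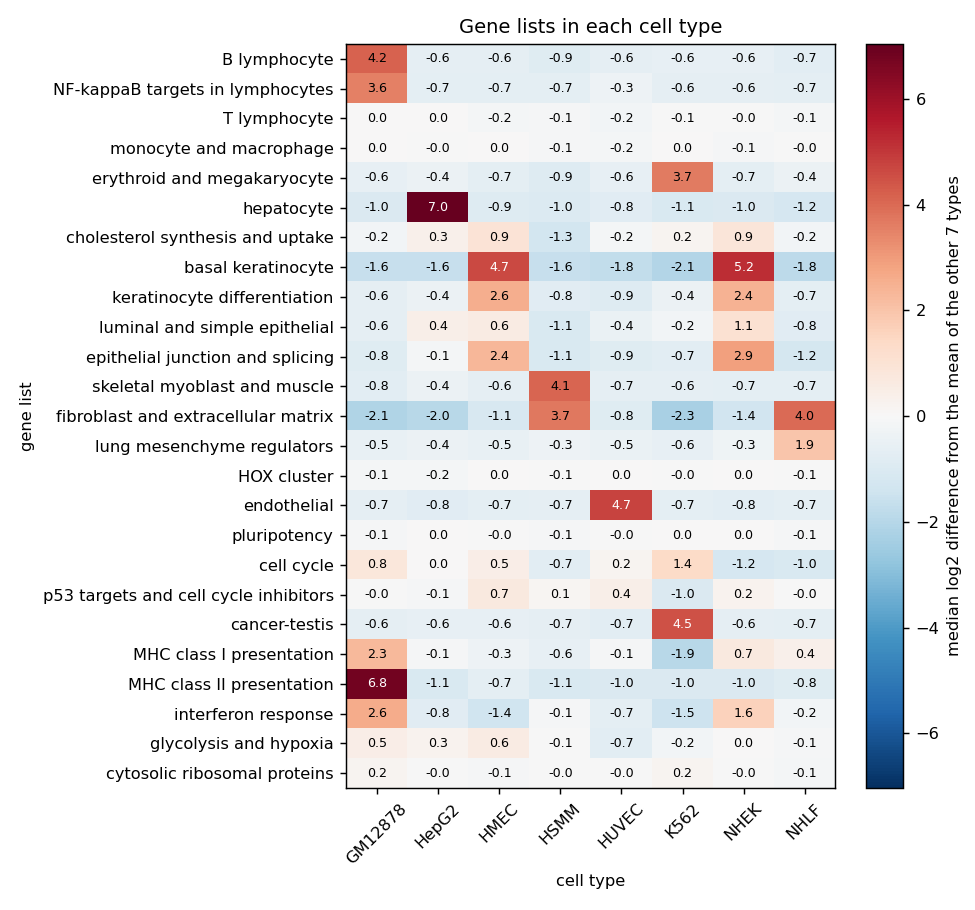
Median log2 difference of each of 25 gene lists (rows) in each of 8 cell types (columns) from the mean of the other 7 types. Lineage lists stand out in their own types, such as hepatocyte in HepG2 (7.04), MHC class II in GM12878 (6.78) and basal keratinocyte in NHEK (5.21).

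In GM12878, all 20 B lymphocyte, 15 of 16 NF-kappaB target and 12 of 13 MHC class II genes had their highest mean of the 8 types. The median levels of the interferon response and MHC class I lists were also highest there, at log2 7.31 and 9.70. Among the genes highest in it, immunoglobulin lambda (IGL) reached log2 12.36 ± 0.21, the surface protein CD48 11.24 ± 0.33, HLA-DRA 11.67 ± 0.21, HLA-DQA1 10.97 ± 0.32, the plasma cell receptor TNFRSF17 10.45 ± 0.19 and immunoglobulin mu (IGHM) 11.01 ± 0.24 (SD, n = 2). Their margins over the next type were 8.20, 8.17, 8.03, 7.91, 7.54 and 7.51 (adjusted p at most 1.05e-08). HLA-DRB1, IGLV2-14, CYTIP and RGS1 followed with margins of 7.44, 7.40, 7.33 and 7.28. IGL probe sets share sequence between genes, 5 of its 11 probe sets had the other sign, and its margin was 0.95 with the mean of all of them. IGHM had 1 of 5 such probe sets. Genes lowest in GM12878 were the tight junction protein TJP1 at 2.66 ± 0.02, the actin-binding TPM1 at 3.93 ± 0.52, NCKAP1 at 4.36 ± 0.63, IGF2BP2 at 3.26 ± 0.06 and LAPTM4B at 6.69 ± 0.11 (SD, n = 2), with K562 or HUVEC next at margins of 5.18, 4.76, 4.61, 4.48 and 4.14. For TJP1, 1 of 3 probe sets had the other sign.

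All 20 B lymphocyte genes were higher in GM12878 than in the mean of the other types (20 adjusted over the list alone, median log2 difference 4.15, camera adjusted p = 8.16e-20). The coactivator POU2AF1 led with a difference of 7.96, then MS4A1 (CD20) with 6.91, LY86 with 6.29 and FCER2 (CD23) with 5.87. All 16 NF-kappaB targets were higher (16 adjusted over the list alone, median 3.57, adjusted p = 2.85e-14), among them CCR7 by 7.11, BCL2A1 by 6.74, EBI3 by 5.88 and CCL4 by 4.96. MHC class II genes were higher for 11 of 13 (11 adjusted over the list alone, median 6.78, adjusted p = 4.41e-13), with HLA-DPA1 by 7.90 and the invariant chain CD74 by 7.87 beside HLA-DRA. Interferon response genes were higher for 21 of 23 and lower for 1 (21 and 1 adjusted over the list alone, median 2.59, adjusted p = 3.25e-12), including IFI44L by 6.37, MX1 by 5.81 and MX2 by 4.31. MHC class I presentation genes were higher for 14 of 16 and lower for 1 (14 and 1 adjusted over the list alone, median 2.27, adjusted p = 7.36e-08), among them the immunoproteasome subunits PSMB9 by 4.75 and PSMB8 by 3.52. The T lymphocyte list was not called in any of the 8 types, with the lowest adjusted p of 0.0741 in HUVEC, where 5 of 16 genes were lower (5 adjusted over the list alone). Its member LCK, chosen after its value was seen, was higher in GM12878 by 5.12 (adjusted p = 4.2e-13). Nor was the monocyte and macrophage list called in any type, with a lowest adjusted p of 0.306 in GM12878, where 3 of 12 genes were higher (3 adjusted over the list alone).

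K562 combined erythroid genes, embryonic and alpha globins among them, with cancer-testis genes, and its MHC class I list had the lowest median level of the 8 types at log2 4.76. The alpha globin HBA2 reached log2 12.07 ± 0.15, the embryonic globins HBZ and HBE1 11.30 ± 0.07 and 12.48 ± 0.06, the cancer-testis genes GAGE7 11.76 ± 0.09 and MAGEA3 10.85 ± 0.05, and the erythroid membrane protein RHAG 10.47 ± 0.27 (SD, n = 3). Margins over the next type were 8.77 for HBA2, 8.62 for GAGE7, 8.30 for HBZ, 8.12 for HBE1, 8.02 for HBA1, 7.79 for MAGEA3 and 7.11 for RHAG (adjusted p at most 1.58e-07). MAGEA6, MAGEA12 and PRAME followed with 7.62, 7.58 and 7.32. Probe sets within the alpha globin, MAGEA and GAGE families can bind transcripts of their relatives, so which member was expressed is uncertain. The next type for HBE1 was NHLF at 4.36 ± 1.92 (SD, n = 2), where 1 of the 2 arrays read 5.72. Lowest in K562 were the cytoskeletal SEPTIN10 at 2.59 ± 0.19, the adhesion molecule ALCAM at 2.87 ± 0.22, the glutathione peroxidase GPX1 at 2.66 ± 0.09, the actin-bundling PLS3 at 2.89 ± 0.18 and MARCKS at 3.78 ± 0.14 (SD, n = 3), at margins of 6.28, 6.17, 5.86, 5.78 and 5.59.

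Erythroid and megakaryocyte genes were higher in K562 for 17 of 20 (17 adjusted over the list alone, median 3.68, adjusted p = 7.94e-11), with the transcription factor KLF1 up by 5.63. Cancer-testis genes were higher for 15 of 20 (15 adjusted over the list alone, median 4.49, adjusted p = 1.48e-10), among them SSX1 by 6.56. MHC class I presentation genes were lower for 12 of 16 and higher for 1 (12 and 1 adjusted over the list alone, median -1.94, adjusted p = 1.13e-05). HLA-C fell by 5.76 to 4.58 ± 0.22, HLA-B fell by 5.27 to 4.34 ± 0.21, and HLA-F fell by 4.34 to 3.36 ± 0.38 (SD, n = 3). The p53 targets and cell cycle inhibitors were lower for 10 of 17 (12 adjusted over the list alone, median -1.01, adjusted p = 0.000105), led by CDKN1A (p21) at -4.31, FAS at -4.01, TP53I3 at -3.13 and CDKN2A (p16) at -3.07. Cell cycle genes were higher for 26 of 30 (26 adjusted over the list alone, median 1.36, adjusted p = 1.28e-05; adjusted p = 0.416 with an estimated correlation), such as MCM4 by 2.36, CDC6 by 2.30 and CCNA2 by 2.24. Cytosolic ribosomal protein genes were higher for 19 of 30 (19 adjusted over the list alone) by a median of 0.20 (adjusted p = 0.0065; adjusted p = 0.506 with an estimated correlation). Among T lymphocyte genes, CD3D was higher in K562 by 4.14 (adjusted p = 6.29e-12), chosen after its value was seen.

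Set directly against GM12878, K562 had 1332 higher and 1251 lower genes. Erythroid genes (15 of 20) and cancer-testis genes (15 of 20) were higher in K562, and MHC class II (11 of 13) and B lymphocyte genes (19 of 20) were lower. HBE1 was higher in K562 by 9.37 ± 0.52 (SE), HBA2 by 9.26 ± 0.18, the neuropeptide neuromedin U (NMU) by 9.20 ± 0.58, GAGE7 by 8.75 ± 0.16, HBZ by 8.38 ± 0.17 and HBA1 by 8.14 ± 0.17 (SE; adjusted p at most 4.14e-08). MAGEA3, MAGEA6, MAGEA12 and RHAG followed at 7.98, 7.86, 7.71 and 7.49. On the other side, IGL fell by 9.48 ± 0.40 (SE), HLA-DPA1 fell by 9.18 ± 0.39, HLA-DRA fell by 8.36 ± 0.23, CD74 fell by 8.32 ± 0.23, CD48 fell by 8.21 ± 0.16 and POU2AF1 fell by 8.20 ± 0.13 (SE; adjusted p at most 6.04e-10). HLA-DRB1, PLAC8, HLA-DQA1 and IGHM differed by -8.10, -8.09, -7.91 and -7.86.

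Lower in K562 than in GM12878 were 19 of 20 B lymphocyte genes (19 adjusted over the list alone, adjusted p = 1.2e-19), 15 of 16 NF-kappaB targets (15 adjusted over the list alone, adjusted p = 5.58e-15), 11 of 13 MHC class II genes (11 adjusted over the list alone, adjusted p = 3.93e-14), 14 of 16 MHC class I genes (14 adjusted over the list alone, adjusted p = 6.88e-12) and 18 of 23 interferon response genes (19 adjusted over the list alone, adjusted p = 4.75e-14). Their median log2 differences were -4.32, -4.11, -7.09, -3.28 and -3.59. HLA-B differed by -7.52, PSMB8 by -6.16, TAP1 by -5.00, MX1 by -6.96, CCR7 by -6.69 and TNFAIP3 by -5.11. Higher were 15 of 20 erythroid genes (15 adjusted over the list alone, median 3.50, adjusted p = 9.67e-13), including TAL1 by 5.73, KLF1 by 5.62 and GATA1 by 4.56, and 15 of 20 cancer-testis genes (15 adjusted over the list alone, median 4.49, adjusted p = 1.48e-13). For p53 targets, 8 of 17 were lower and 3 higher (8 and 3 adjusted over the list alone, median -0.17, adjusted p = 0.00828; adjusted p = 0.139 with an estimated correlation). FAS was at -5.77, CDKN1A at -4.29 and CDKN2A at -2.80, while GDF15 was higher by 1.62. Glycolysis and hypoxia genes were lower for 9 of 21 and higher for 2 (11 and 2 adjusted over the list alone, median -0.83, adjusted p = 0.0221; adjusted p = 0.909 with an estimated correlation), with ENO2 at -2.35 and PKM at -1.56. Keratins of simple epithelia were higher in K562, KRT18 by 7.13 and KRT19 by 4.83, and so was EPCAM by 6.55, though their list was not called (5 higher and 3 lower of 16, 5 and 3 adjusted over the list alone, adjusted p = 0.528).

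HepG2 expressed the hepatocyte genes (29 of 32 higher than in the mean of the other types), several of them near the top of the arrays. Its genes highest over the next type were the plasma proteins AHSG at log2 12.85 ± 0.29, APOB at 12.67 ± 0.04, APOH at 12.72 ± 0.01, RBP4 at 11.73 ± 0.15, alpha-fetoprotein (AFP) at 12.97 ± 0.08, ITIH2 at 12.08 ± 0.05 and transferrin (TF) at 12.94 ± 0.17 (SD, n = 2). Their margins were 9.01, 9.00, 8.87, 8.72, 8.72, 8.60 and 8.57 (adjusted p at most 5.53e-07). APOA1, APOA2 and the fatty acid binding FABP1 followed at 8.37, 8.33 and 8.21. For AHSG, APOB, APOH, AFP, TF and APOA2 the next type was HUVEC, whose arrays disagreed (SD 1.33 to 2.12, n = 2). Lowest in HepG2 were lactate dehydrogenase B (LDHB) at 3.78 ± 0.30 against 11.47 in NHEK, SRI at 3.17 ± 0.02, the mesenchymal filament vimentin (VIM) at 3.25 ± 0.03 against 9.59 in GM12878, moesin (MSN) at 2.71 ± 0.06 and EID1 at 3.77 ± 0.48 (SD, n = 2), at margins of 7.69, 6.87, 6.33, 5.64 and 5.55. Without HepG2 replicate 2, which differed from replicate 1 more than in any other type, 323 genes in place of 198 were lower in HepG2.

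Hepatocyte genes were higher in HepG2 for 29 of 32 (29 adjusted over the list alone, median 7.04, adjusted p = 4.95e-26), with albumin (ALB) up by 9.47 beside APOB, APOH and AHSG. The list for cholesterol synthesis and uptake was not called in HepG2 (3 of 14 higher and 3 lower, 3 and 4 adjusted over the list alone, median 0.34, mean -0.20, adjusted p = 0.679), and its members parted. The sterol sensor INSIG1 was at 2.97 ± 0.02 (SD, n = 2) against a mean of 8.78 in the other types, and IDI1 was lower by a difference of -1.11, while the synthesis enzymes SQLE and CYP51A1 were each higher by 1.03. In other types the list was higher in HMEC (10 of 14, 13 adjusted over the list alone, median 0.93, adjusted p = 1.69e-07; adjusted p = 0.0828 with an estimated correlation) and NHEK (11 of 14, 11 adjusted over the list alone, median 0.86, adjusted p = 2.5e-06; adjusted p = 0.113 with an estimated correlation). It was lower in HSMM for 13 of 14 (13 adjusted over the list alone, median -1.30, adjusted p = 2.5e-06; adjusted p = 0.113 with an estimated correlation), with EBP at -2.24 and SQLE at -2.22.

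HUVEC was set apart by endothelial genes, 28 of 29 of which were higher than in the mean of the other types. Von Willebrand factor (VWF) reached log2 11.66 ± 0.02, the receptor CD93 11.14 ± 0.00, MMRN1 9.74 ± 0.02, vascular endothelial cadherin (CDH5) 10.22 ± 0.07, PECAM1 (CD31) 11.29 ± 0.07, BMP6 9.62 ± 0.01 and ESM1 8.95 ± 0.23 (SD, n = 2). Their margins were 8.37, 7.61, 7.15, 7.15, 6.62, 6.03 and 5.78 (adjusted p at most 1.98e-10). FABP4, the matrix protein MGP and the homeobox gene MEOX2 followed at 5.73, 5.42 and 5.39. MEOX2 had another probe set of the other sign. The 5 genes lowest in HUVEC were ASAH1, TOM1L1, HDDC2, NF1 and RABGEF1, at margins of 1.97, 1.84, 1.70, 1.05 and 1.01 (adjusted p at most 0.0273). None of these 5 calls held under every alternative, and 6 of 9 probe sets of NF1, 1 of 4 of ASAH1 and 1 of 2 of HDDC2 had the other sign. Endothelial genes were higher for 28 of 29 (28 adjusted over the list alone, median 4.73, adjusted p = 3.85e-37), with ICAM2 up by 6.26. Glycolysis and hypoxia genes were lower for 9 of 21 and higher for 2 (13 and 2 adjusted over the list alone, median -0.72, adjusted p = 0.00448; adjusted p = 0.451 with an estimated correlation), with VEGFA at -3.31, SLC2A1 (GLUT1) at -2.74 and HK2 at -2.69. HOX cluster genes went both ways (6 of 25 higher and 4 lower, 7 and 4 adjusted over the list alone, median 0.02, adjusted p = 0.224), with HOXB7 higher by 3.23, HOXD1 higher by 2.16 and HOXC6 at -2.07. In HUVEC replicate 2, transcripts of liver cells stood above replicate 1, with ALB at 6.52 against 3.01, AFP at 5.76 against 2.76, TF at 5.60 against 3.14 and APOH at 5.05 against 2.65.

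**Figure D3:**
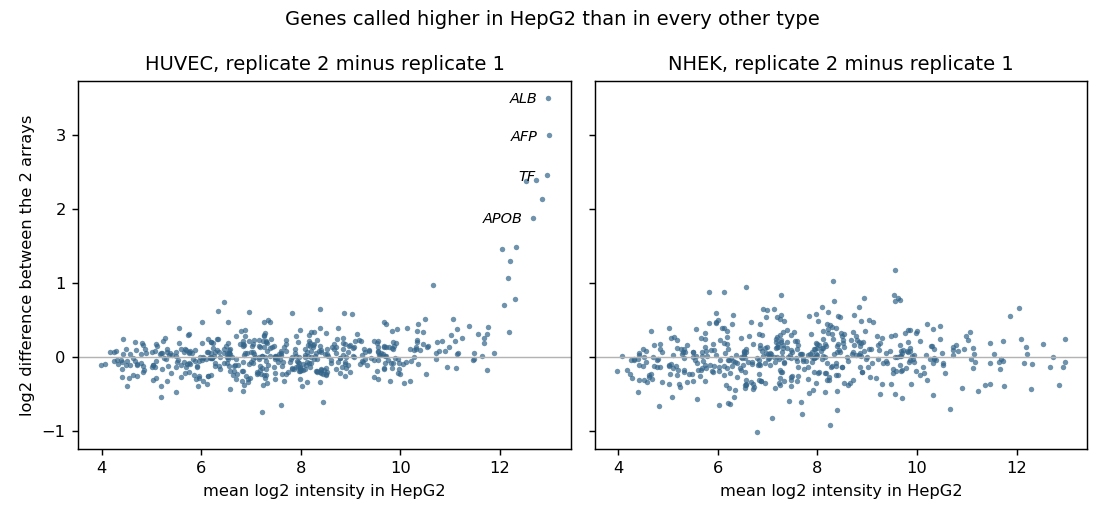
Genes called higher in HepG2, each a point, with mean log2 intensity in HepG2 on the horizontal axis and the log2 difference between replicates 2 and 1 of HUVEC (left) or NHEK (right) on the vertical axis. In HUVEC the brightest HepG2 genes rise, ALB by 3.51 and TF by 2.46, and in NHEK they stay near 0.

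Few genes were higher in HMEC than in every other type, and NHEK was the type closest to it. These included CCN6 at log2 6.93 ± 0.16, the epithelial sodium channel subunit SCNN1A at 10.31 ± 0.26, the simple epithelial keratin KRT7 at 10.31 ± 0.44, MIA at 7.67 ± 0.17, TREM2 at 6.55 ± 0.43, the kallikrein proteases KLK6 and KLK7 at 6.25 ± 0.08 and 8.56 ± 0.29, and the glutamate transporter SLC1A6 at 6.37 ± 0.31 (SD, n = 2). Their margins were 4.06, 3.91, 3.41, 3.19, 3.15, 2.83, 2.63 and 2.72, with NHEK next except for SLC1A6 (adjusted p at most 0.00804). The innate receptor TLR2 and GPM6B followed at 2.54 and 2.20 (adjusted p = 0.048 and 0.03). The calls for TLR2, GPM6B and SCNN1A each ended under some alternatives, and 2 of 3 SCNN1A probe sets had the other sign. Without NHEK replicate 1, 13 genes in place of 21 were higher in HMEC. The 4 genes lowest in HMEC were the lipid droplet protein PLIN2, TBL1X, REPIN1 and RHOBTB3, the first at a margin of 2.50 and the last pair at 1.72 and 1.42, and each call ended under at least 1 alternative. PLIN2, TBL1X and RHOBTB3 each had 1 probe set of the other sign.

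Basal keratinocyte genes were higher in HMEC than in the mean of the other types for 16 of 17 (16 adjusted over the list alone, median 4.67, adjusted p = 9.23e-28), led by KRT14 with a difference of 8.56, S100A2 with 7.59, KRT5 with 7.13 and KRT15 with 6.21. Epithelial junction and splicing genes were higher for 14 of 18 (14 adjusted over the list alone, median 2.36, adjusted p = 2.39e-14), such as E-cadherin (CDH1) by 5.59, desmoplakin (DSP) by 4.67 and the splicing factor ESRP1 by 4.40. The luminal and simple epithelial list was also higher (8 of 16 higher and 1 lower, 8 and 2 adjusted over the list alone, median 0.57, adjusted p = 0.000347), with SPINT2 up by 4.87 and GATA3 by 2.72 beside KRT7. Its median level was log2 3.76 in HMEC, below NHEK (5.40) and HepG2 (3.93). Of its members 2 had their highest mean in HMEC, 3 in NHEK and 7 in HepG2. Keratinocyte differentiation genes were higher for 16 of 25 and lower for 1 (16 and 2 adjusted over the list alone, median 2.57, adjusted p = 1.63e-13), and p53 targets for 11 of 17 with 2 lower (12 and 3 adjusted over the list alone, median 0.71, adjusted p = 4.12e-05). Interferon response genes were lower for 19 of 23 (20 adjusted over the list alone, median -1.39, adjusted p = 3.67e-11), with IFITM1 at -3.61 and BST2 at -2.38. This low level was not particular to HMEC. The median level of the list was log2 3.30 in HMEC, 3.19 in K562, 3.52 in HUVEC and 3.59 in HepG2. It was far higher in GM12878 (7.31) and NHEK (6.20), which are part of the mean of the other types. Glycolysis and hypoxia genes were higher for 9 of 21 (12 adjusted over the list alone, where 1 was lower; median 0.56, adjusted p = 2.38e-05; adjusted p = 0.253 with an estimated correlation).

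In NHEK, 16 of 17 basal keratinocyte genes and 21 of 25 keratinocyte differentiation genes were higher than in the mean of the other types. UGT1A4 was at log2 9.13 ± 0.08, UGT1A6 at 8.34 ± 0.23, the cytokine IL18 at 8.27 ± 0.05, the hair keratin KRT31 at 7.39 ± 0.17, podoplanin (PDPN) at 7.91 ± 0.33, CXCL14 at 7.18 ± 0.04 and lipocalin 2 (LCN2) at 7.39 ± 0.50 (SD, n = 2). Their margins were 5.77, 5.16, 4.45, 4.35, 4.05, 3.92 and 3.69 (adjusted p at most 1.13e-06). UPK1B, LGALS7 and sciellin (SCEL) followed at 3.65, 3.63 and 3.60. The UGT1A genes share exons, so their probe sets cannot separate the members, and PDPN had another probe set of the other sign. The mitochondrial thiolase ACAA2 was the 1 gene lower than in every other type, at 3.71 ± 0.25 (SD, n = 2) with a margin of 2.71. Basal keratinocyte genes were higher for 16 of 17 and lower for 1 (16 and 1 adjusted over the list alone, median 5.21, adjusted p = 4.95e-26), with KRT14 by 8.98 and KRT5 by 8.05. Keratinocyte differentiation genes were higher for 21 of 25 (22 adjusted over the list alone, median 2.44, adjusted p = 7.1e-23), with the cornified envelope genes SPRR1B by 7.42 and SPRR1A by 6.70 beside LGALS7 by 7.85. Junction and splicing genes were higher for 16 of 18 (17 adjusted over the list alone, median 2.90, adjusted p = 2.06e-17), with CDH1 by 5.96 and DSP by 5.21. Cell cycle genes were lower for 19 of 30 (25 adjusted over the list alone, median -1.16, adjusted p = 4.74e-06; adjusted p = 0.388 with an estimated correlation), with TOP2A at -1.84 and BUB1 at -1.81. Interferon response genes were higher for 18 of 23 and lower for 1 (19 and 1 adjusted over the list alone, median 1.64, adjusted p = 1.37e-11), IFI27 by 7.10 and OAS1 by 4.44.

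Between the epithelial cultures, the list with the lowest adjusted p was the interferon response, higher in NHEK for 18 of 23 genes. Of the keratinocyte differentiation genes 11 of 25 were higher in NHEK and 4 lower, and of the p53 targets 7 of 17 were lower and 1 higher. For the cell cycle, 7 of 30 genes were lower (adjusted p = 0.386 with an estimated correlation). There were 228 genes higher and 235 lower in NHEK than in HMEC. Without NHEK replicate 1, 118 genes in place of 235 were lower. IFI27 was higher in NHEK by 7.94 ± 0.25 (SE), the matrix protein THBS2 by 7.58 ± 0.12, IFIT1 by 6.14 ± 0.63, IFITM1 by 5.87 ± 0.75, UGT1A4 by 5.78 ± 0.17, IFI6 by 5.37 ± 0.39 and MX1 by 5.34 ± 0.27 (SE; adjusted p at most 0.000332). UGT1A6, OAS1 and ISG15 followed at 5.17, 5.03 and 4.97. Of these 10 genes with the largest rise in NHEK, 7 were interferon response genes. NNMT, a nicotinamide methyltransferase, fell by 6.64 ± 0.25 (SE), GPM6B fell by 6.38 ± 0.39, IGFBP2 fell by 5.05 ± 0.43, the imprinted gene PEG10 fell by 4.78 ± 0.16 and DEPP1 fell by 4.42 ± 0.67 (SE; adjusted p at most 0.00128). SERPINA1, EPS8, CCNA1, CCN6 and SCNN1A differed by -4.33, -4.30, -4.22, -4.06 and -3.91. The SCNN1A call ended without the 4 arrays in which some of another type's brightest genes were faintly raised.

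**Figure D4:**
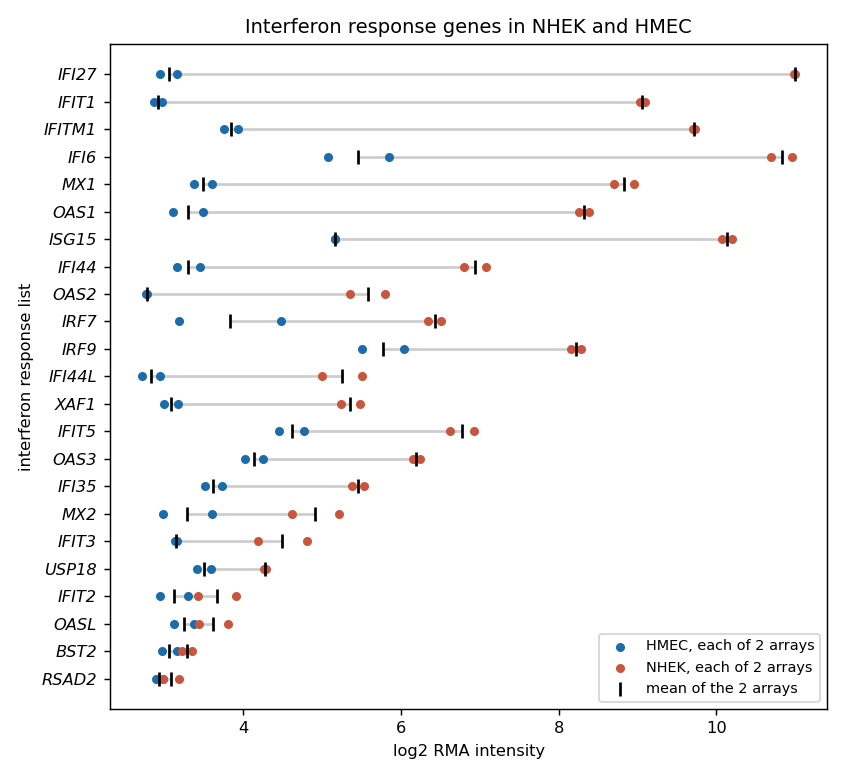
Log2 RMA intensity (horizontal axis) of the 23 interferon response genes (vertical axis) in each of 2 HMEC and 2 NHEK arrays, with a bar at each mean. For IFI27 the means are 3.05 in HMEC and 10.99 in NHEK, and for MX1 3.49 and 8.82.

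In all, 18 of the 23 interferon response genes were higher in NHEK than in HMEC (19 adjusted over the list alone, median 2.42, adjusted p = 9.95e-38). Sensors and effectors in the list included OAS2 by 2.80, the transcription factors IRF7 by 2.60 and IRF9 by 2.44, and XAF1 by 2.27. MHC class I genes were higher for 3 of 16 (13 adjusted over the list alone, where 1 was lower; median 0.78, adjusted p = 3.02e-07), with HLA-B by 1.37, PSME1 by 0.69 and B2M by 0.59. Keratinocyte differentiation genes were higher for 11 of 25 and lower for 4 (12 and 6 adjusted over the list alone, median 0.29, adjusted p = 0.00102). LGALS7 was higher by 3.63, KRT1 by 3.09, filaggrin (FLG) by 2.27 and involucrin (IVL) by 1.99, while KLK6 and KLK7 were at -2.83 and -2.63. Basal keratinocyte genes were higher for 4 of 17 and lower for 1 (5 and 1 adjusted over the list alone, median 0.48, adjusted p = 0.000894), KRT16 by 1.97 and ITGB4 by 1.32, with KRT15 at -0.84. Junction genes were higher for 2 of 18 (2 adjusted over the list alone, median 0.37, adjusted p = 0.00462; adjusted p = 0.156 with an estimated correlation), with CLDN1 by 2.42. Cell cycle genes were lower for 7 of 30 (20 adjusted over the list alone, median -1.29, adjusted p = 4.53e-14; adjusted p = 0.386 with an estimated correlation), such as CCNE2 at -2.21 and RRM2 at -1.87. The p53 targets were lower for 7 of 17 and higher for 1 (7 and 1 adjusted over the list alone, median -0.45, adjusted p = 0.000403), with GDF15 at -1.71, BAX at -1.53 and CDKN1A at -1.13, while CDKN2A was higher by 0.93. Simple keratins parted, with KRT19 higher by 3.49 and KRT7 at -3.41.

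HSMM expressed muscle genes (25 of 29 higher than in the mean of the other types) together with fibroblast and extracellular matrix genes (29 of 32 higher and 2 lower). Cardiac alpha-actin (ACTC1), an early actin of developing muscle, was at log2 12.92 ± 0.15, KLHL41 at 10.44 ± 0.89, the acetylcholine receptor subunit CHRNA1 at 11.52 ± 0.11, the collagen COL11A1 at 10.23 ± 0.35, the myosin light chain MYL11 at 10.19 ± 0.85, troponin TNNI1 at 9.82 ± 1.69, NCAM1 at 9.67 ± 0.50 and the myogenic factor MYF5 at 9.15 ± 0.32 (SD, n = 2). Their margins were 9.49, 7.73, 7.54, 6.83, 6.78, 6.74, 6.61 and 6.27 (adjusted p at most 1.65e-06). CASQ2 and the skeletal actin ACTA1 followed at 6.06 and 5.86. NCAM1 had 1 of 5 probe sets of the other sign. Lowest in HSMM were the peroxiredoxin PRDX2 at 7.41 ± 0.27 against 10.16 in NHLF, PIR, ZFP36L2 and MICB, at margins of 2.75, 2.15, 1.79 and 1.78. The calls for PIR, ZFP36L2 and MICB each ended under at least 1 alternative, and MICB had 1 of 2 probe sets of the other sign. Muscle genes were higher for 25 of 29 (27 adjusted over the list alone, median 4.09, adjusted p = 4.79e-29), with the troponin TNNC1 by 6.89. Fibroblast and extracellular matrix genes were higher for 29 of 32 and lower for 2 (29 and 2 adjusted over the list alone, median 3.72, adjusted p = 4.45e-26), with COL1A2 by 6.96, COL3A1 by 6.81 and COL1A1 by 6.74. The HOX cluster list was called higher (8 of 25 higher and 1 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.0306; adjusted p = 0.282 with an estimated correlation) with a median of -0.05 and a mean of 0.58, as HOXC6 by 3.58, HOXC10 by 3.01, HOXB6 by 2.34 and HOXC13 by 2.17 stood above the rest. Without HSMM replicate 2 the median was 0.04. Cell cycle genes were lower in HSMM for 9 of 30 (9 adjusted over the list alone, median -0.73, adjusted p = 0.00184; adjusted p = 0.586 with an estimated correlation).

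NHLF expressed fibroblast and extracellular matrix genes (31 of 32 higher than in the mean of the other types) together with regulators of lung mesenchyme (10 of 13 higher and 1 lower). The receptor PDGFRA was at log2 10.90 ± 0.20, the chemokine CXCL12 at 9.04 ± 1.13, the forkhead factor FOXF1 at 8.81 ± 0.57, hepatocyte growth factor (HGF) at 8.66 ± 0.10, the smooth muscle actin ACTG2 at 9.24 ± 1.85, PLPPR4 at 8.31 ± 2.05 and the alcohol dehydrogenase ADH1B at 8.04 ± 0.29 (SD, n = 2). Their margins were 7.90, 5.89, 5.87, 5.79, 5.52, 5.45 and 5.07 (adjusted p at most 7.73e-05). CLEC3B, PSG4 and GPR37 followed at 5.04, 4.78 and 4.72. PDGFRA had another probe set of the other sign, and PSG4 belongs to a family of close relatives that its probe set may not separate. The 3 genes lowest in NHLF were CHD7, SINHCAF and RNF44 at margins of 1.83, 1.45 and 1.43, and each call ended under at least 1 alternative. CHD7 had 1 of 2 probe sets of the other sign. Fibroblast and extracellular matrix genes were higher for 31 of 32 (31 adjusted over the list alone, median 4.01, adjusted p = 1.1e-32), with decorin (DCN) by 8.36, COL3A1 by 7.77, COL1A2 by 7.43 and periostin (POSTN) by 7.02. Lung mesenchyme regulators were higher for 10 of 13 and lower for 1 (10 and 1 adjusted over the list alone, median 1.95, adjusted p = 3.8e-08), with WNT5A by 4.79, FOXF2 by 4.64, TBX2 by 4.28 and TCF21 by 4.06. HOX cluster genes were higher for 6 of 25 and lower for 5 (6 and 5 adjusted over the list alone, median -0.05, mean 0.19, adjusted p = 0.394), with HOXB6 higher by 3.75 and HOXB5 by 2.48. Cell cycle genes were lower for 18 of 30 (22 adjusted over the list alone, median -1.05, adjusted p = 0.000106; adjusted p = 0.479 with an estimated correlation), and the NHLF arrays differed in them by a median of -1.71 (replicate 2 minus replicate 1).

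Set against HSMM, NHLF had 606 higher and 500 lower genes. Lung mesenchyme regulators were higher in NHLF (8 of 13) and muscle genes lower (22 of 29). The Wnt antagonist SFRP1 was higher in NHLF by 8.46 ± 0.24 (SE), PDGFRA by 7.90 ± 0.15, latexin (LXN) by 7.47 ± 0.15, the laminin LAMA4 by 6.81 ± 0.34, SPON2 by 6.54 ± 0.21, ENPP2 (autotaxin) by 6.51 ± 0.27 and the collagenase MMP1 by 6.51 ± 0.71 (SE; adjusted p at most 2.87e-05). RGCC followed at 6.08, then FOXF1 with a mean of 8.81 in NHLF and 2.81 in HSMM, and CXCL12 with 9.04 and 3.04. ACTC1 fell by 9.49 ± 0.16 (SE), CHRNA1 fell by 8.69 ± 0.12, KLHL41 fell by 7.73 ± 0.29, TNNC1 fell by 7.19 ± 0.48 and TNNI1 fell by 7.02 ± 0.51 (SE; adjusted p at most 6.18e-07). COL11A1, MYL11, NCAM1, ACTA1 and MYF5 differed by -6.83, -6.78, -6.72, -6.45 and -6.38. Muscle genes were lower in NHLF for 22 of 29 (24 adjusted over the list alone, median -4.20, adjusted p = 8.53e-34), desmin (DES) at -5.58 and MYOD1 at -4.78 among them. Lung mesenchyme regulators were higher for 8 of 13 (9 adjusted over the list alone, median 0.95, adjusted p = 1.9e-10), with FOXF2 by 4.73, TCF21 by 4.08 and TBX2 by 3.99. Cholesterol genes were higher for 9 of 14 (11 adjusted over the list alone, median 1.04, adjusted p = 3.79e-07; adjusted p = 0.179 with an estimated correlation), with INSIG1 by 2.59 and LSS by 2.04. MHC class I genes were higher for 5 of 16 (10 adjusted over the list alone, median 0.78, adjusted p = 1.46e-06), with PSMB9 by 3.14 and PSMB8 by 2.08. Matrix genes were higher for 10 of 32 and lower for 4 (11 and 6 adjusted over the list alone, median 0.30, adjusted p = 0.023; adjusted p = 0.705 with an estimated correlation), PRRX1 by 4.17 and DCN by 3.73 against elastin (ELN) at -3.22 and CDH2 at -2.80. HOX genes were not called as a list (3 higher and 5 lower of 25, 4 and 6 adjusted over the list alone, adjusted p = 0.683), with HOXC6 at -3.50 and HOXC10 at -3.45 against HOXB6 higher by 1.24.

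The epithelial cultures HMEC and NHEK differed from the mesenchymal cultures HSMM and NHLF in 717 higher and 893 lower genes by their means. With the arrays as replicates, SE and p-values here measured the spread between arrays of a type, not between the types of a group. In 588 of the higher and 634 of the lower genes all 4 epithelial arrays lay beyond all 4 mesenchymal ones (by chance 1.43% of genes not selected for a difference), and in the rest the groups overlapped. Basal keratinocyte (16 of 17) and junction and splicing genes (17 of 18) were higher, and extracellular matrix genes (30 of 32) lower, in the epithelial cultures. KRT14 was higher in the epithelial cultures by 10.30 ± 0.08 (SE), KRT5 by 8.91 ± 0.11, maspin (SERPINB5) by 8.89 ± 0.08, FGFBP1 by 8.70 ± 0.11, cystatin A (CSTA) by 8.13 ± 0.26 and stratifin (SFN) by 7.86 ± 0.14 (SE; adjusted p at most 5.25e-11). FXYD3, SPRR1B, CDH1 and the calgranulin S100A8 followed at 7.57, 7.53, 7.42 and 7.39. COL1A2 fell by 8.79 ± 0.18 (SE), COL3A1 fell by 8.43 ± 0.19, pentraxin 3 (PTX3) fell by 7.96 ± 0.19, LRRC17 fell by 7.57 ± 0.27 and DCN fell by 7.18 ± 0.17 (SE; adjusted p at most 1.37e-10). The BMP antagonist GREM1, IGFBP5, lumican (LUM), CEMIP and COL1A1 differed by -7.17, -7.07, -7.01, -6.97 and -6.89.

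Junction and splicing genes were higher in the epithelial cultures for 17 of 18 (17 adjusted over the list alone, median 3.72, adjusted p = 1.64e-16), with EPCAM by 5.27, plakoglobin (JUP) by 4.96, ESRP1 by 4.77 and ESRP2 by 4.40. Basal keratinocyte genes were higher for 16 of 17 and lower for 1 (16 and 1 adjusted over the list alone, median 5.52, adjusted p = 2.86e-21), LAMB3 by 7.38 and S100A2 by 6.74, with DST at -1.98. Differentiation genes were higher for 22 of 25 (22 adjusted over the list alone, median 2.97, adjusted p = 3.5e-20) and luminal genes for 11 of 16 (11 adjusted over the list alone, where 1 was lower; median 1.04, adjusted p = 1.71e-07). Cholesterol genes were higher for 13 of 14 (13 adjusted over the list alone, median 1.45, adjusted p = 4.03e-08; adjusted p = 0.148 with an estimated correlation), EBP by 2.58 and HMGCS1 by 1.87. Matrix genes were lower for 30 of 32 and higher for 1 (30 and 1 adjusted over the list alone, median -4.54, adjusted p = 9.73e-28). Muscle genes were lower for 23 of 29 (23 adjusted over the list alone, median -2.41, adjusted p = 2.38e-16), ITGA7 at -4.00 and MEF2C at -3.97 among them. The median level of the list was 7.93 in HSMM but 2.95 in NHLF, below HMEC (3.25) and NHEK (3.10). Lung mesenchyme regulators were lower for 9 of 13 (9 adjusted over the list alone, median -0.76, adjusted p = 1.12e-05), WNT5A at -3.52, with a median level of 6.01 in NHLF and of 3.21 in HSMM, near HMEC (3.13) and NHEK (2.98).

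The established lines GM12878, HepG2 and K562 come from different lineages, but GM12878 and K562 are both of blood origin. None of the 5 finite-lifespan cultures is, so established status and blood origin partly overlap here and cannot be fully told apart. The largest differences of the lines from the cultures were falls. With the cell types as replicates (3 against 5), 57 genes were higher and 121 lower in the lines. IGFBP7 fell by 8.29 ± 0.26 (SE), the matrix protein EFEMP1 fell by 8.17 ± 0.58, SRPX fell by 7.73 ± 0.36, caveolin 1 (CAV1) fell by 7.70 ± 0.78, myoferlin (MYOF) fell by 7.64 ± 0.17 and EMP1 fell by 7.60 ± 0.14 (SE; adjusted p at most 0.00572). The protease PRSS23, the Wnt regulator DKK3, the protease HTRA1 and peroxidasin (PXDN) differed by -7.45, -7.41, -7.09 and -6.94. MYOF averaged 3.23 in the lines and 10.87 in the cultures, and EMP1 3.20 and 10.80. Higher in the lines were COCH by 4.91 ± 0.77 (SE), the tryptophan pathway enzyme KYNU by 4.21 ± 0.63, ALDH5A1 by 3.93 ± 0.35, TESC by 3.33 ± 0.40 and IQGAP2 by 3.19 ± 0.56 (SE; adjusted p at most 0.0442). RNASET2, PIP5K1B, the phosphatase PTP4A3, CTH and the purine synthesis enzyme PPAT followed at 3.15, 2.98, 2.87, 2.69 and 2.47. The counts depended on which types were included, from 23 (without HSMM) to 229 (without HepG2) higher genes and from 69 (without NHLF) to 284 (without HepG2) lower genes. The calls of COCH, KYNU, IQGAP2, CTH and PPAT ended without some of the types.

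No list held in this comparison with an estimated correlation. The extracellular matrix list was lower with 1 gene of 32 called (2 adjusted over the list alone, median -2.91, adjusted p = 6.47e-09; adjusted p = 0.582 with an estimated correlation), that gene being CDH11 at -5.78. The median level of this list was high only in HSMM (9.54) and NHLF (10.25). It was 3.98 to 4.25 in NHEK, HUVEC and HMEC, and 3.19 to 3.36 in the lines. Cell cycle genes were higher with 2 of 30 called (3 adjusted over the list alone, median 1.17, adjusted p = 2.03e-07; adjusted p = 0.785 with an estimated correlation), MCM3 by 1.82 and CCNE1 by 1.64. Among p53 targets TP53I3 at -3.47 was the 1 gene of 17 called (1 adjusted over the list alone, median -0.51, adjusted p = 0.00462; adjusted p = 0.4 with an estimated correlation). The MHC class I and the glycolysis and hypoxia lists were not called (medians -0.10 and 0.20, adjusted p = 0.889 for each), and the mean of the glycolysis list was -0.04.

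H1 was measured on another array design in a table normalized separately, so platform and cell type cannot be told apart and percentiles within arrays were compared without a test. Genes of the pluripotent state stood out. Of 17 pluripotency genes, 15 ranked above the mean of every other type in both H1 arrays. The median percentile of the 17 in H1 was 91.0, against 32.7 in HMEC, the other type with the highest median. Some of the 15 were only slightly above, TERT at 49.9 against 48.9 in HepG2 and LEFTY1 at 44.4 against 37.3 in NHEK. UTF1 and LEFTY2 also ranked low in H1, at 48.6 and 48.7. In the 8 types of the main table the pluripotency list was not called, with a lowest adjusted p of 0.328 in GM12878 (3 of 17 lower, 3 adjusted over the list alone). DPPA4 was at percentile 91.0 ± 0.2 in H1 and at most 9.68 elsewhere, NANOG at 95.5 ± 0.2 and 24.6, and LIN28A at 99.0 ± 0.1 and 35.7 (SD, n = 2). NTS at 89.8, CNMD at 89.0, L1TD1 at 98.0, CLDN10 at 85.6, IDO1 at 89.8, NELL2 at 89.1, CHGA at 78.1, SH3GL2 at 61.2, GPC4 at 94.8 and SLC12A1 at 63.8 completed the named set with POU5F1P3 at 97.0 and POU5F1P4 at 97.4. The last pair can also bind transcripts of POU5F1, from which they derive. GAL was at 91.4 with K562 at 93.1, and SOX2 at 32.2 with HMEC at 32.9. With the mean of its probe sets, SOX2 stood 45.6 points above the next type.

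Farthest below every other type in H1 were SP100 at percentile 3.82 with a lowest other of 69.5, SP140L at 13.5 against 66.8, CXCL8 (interleukin 8) at 2.62 against 50.2 and TICAM1 at 15.8 against 61.5. MBD2 was at 24.0 against 86.9, but with the mean of its probe sets H1 stood above the highest other type by 2.29 points. Cell cycle genes ranked above every other type for 12 of 30 and below for 1, and HOX genes ranked below every other type for 16 of 25 and above for 1. Over all genes, 1935 ranked above every other type in both H1 arrays and 2721 below, 174 of the former by 20 points or more. The H1 arrays had a correlation of 0.997 across probe sets, which are not independent replicates, and 0.104% of the shared probe sets differed over 2-fold between them.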

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

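Leaving out 4 arrays (HUVEC 2, HMEC 2, HSMM 1 and NHLF 2) was chosen only after the data were seen, and the other alternatives before. In these 4 arrays some of another type's brightest genes were faintly raised. Among 30 counts and comparisons, the probe set with the largest variance and median centring moved none by more than 1.5 times. Of 264 results for the genes named by rule and for 23 lists in the types they fit, 29 changed their call under at least 1 alternative. These results were not recounted at 4-fold. For H1 only a gap above every other type that turned negative was counted. SOX2 in H1, which stood above the other types with the mean of its probe sets, is thus not among the 29. Most list calls lost with an estimated correlation lie outside these 264. The causes were not tested, except that a higher fold minimum lowers counts by construction. Fewer arrays or types lower power, yet some counts rose without them. Without HepG2, 229 genes in place of 57 were higher in the established lines.

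With at least 4-fold, genes higher than in every other type numbered 199 in GM12878, 240 in HepG2, 12 in HMEC, 88 in HSMM, 74 in HUVEC, 115 in K562, 26 in NHEK and 81 in NHLF. Genes lower numbered 50 in GM12878, 49 in HepG2, 1 in HMEC, 2 in HSMM, 0 in HUVEC, 70 in K562 and 0 in NHLF. At an unadjusted p under 0.05 in limma, the last zeros became 1 in HUVEC and stayed 0 in NHLF. The comparisons gave 300 and 371 for epithelial against mesenchymal cultures, 420 and 614 for K562 against GM12878, 99 and 70 for NHEK against HMEC, 261 and 212 for NHLF against HSMM, and 11 higher genes for the established lines. The estimated correlation left 62 list calls by type and 22 between groups.

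Most of the other changes lay in the short lists of genes lower than in every other type. Without the 4 arrays, 1 gene was lower in HMEC, 4 in HSMM and 0 in HUVEC (20 at an unadjusted p under 0.05 in limma). With the mean of all probe sets, 2 were lower in HMEC and 3 in HUVEC. Quantile normalization gave 3 lower in HUVEC and 4 in NHEK, removal of dim genes gave 4 in NHEK, and trend and robust settings gave 3 in HUVEC, 2 in NHEK and 27 higher in the established lines. With arrays in place of cell types as replicates, 698 genes were higher and 763 lower in the established lines, as the arrays of a type are not independent of each other.

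Leaving out 1 array at a time left types with 1 array, which was assumed to vary like the others. Genes lower ranged from 2 to 4 in HMEC, 7 (without HSMM replicate 1) to 13 in HSMM, 2 to 6 in HUVEC, 1 to 4 in NHEK, 1 to 3 in NHLF and 138 (without HepG2 replicate 1) to 323 (without HepG2 replicate 2) in HepG2. Genes higher in HMEC ranged from 13 (without NHEK replicate 1) to 22, and genes lower in NHEK than in HMEC from 118 (without NHEK replicate 1) to 297 (without NHLF replicate 1). Leaving out 1 cell type at a time, 23 (without HSMM) to 229 (without HepG2) genes were higher and 69 (without NHLF) to 284 (without HepG2) lower in the established lines. The ratio of distances between and within types ranged from 12.4 to 16.1. The median of the HOX cluster list in HSMM was 0.0421 without HSMM replicate 2, against -0.05 with all arrays, and its call ended without HSMM replicate 1 (median -0.0186) and without HepG2 replicate 2 (median -0.0591).

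With the replicate number as a block, genes lower in HUVEC were 2 in place of 5, and no other count moved by more than 1.5 times. The calls of 7 named genes ended, TLR2, GPM6B and RHOBTB3 in HMEC, MICB in HSMM, and ASAH1, NF1 and RABGEF1 in HUVEC (adjusted p from 0.0899 for TLR2 to 0.12 for RHOBTB3). NHEK against HMEC gave 231 higher and 223 lower genes, NHLF against HSMM 603 and 492, K562 against GM12878 1419 and 1300, epithelial against mesenchymal cultures 719 and 894, and the established lines 52 and 118. Over 28 pairs of types, differences between replicates 2 and 1 had correlations across genes from -0.22 to 0.30 with a median of 0.005. They lay over 0.1 in 5 pairs, GM12878 with HepG2 (0.302), HMEC with HSMM (0.202), HepG2 with HSMM (0.127) and with HMEC (0.109), and HSMM with NHEK (0.107), and under -0.1 in 2. The numbers did not show a batch shared by all types, and one shared by some of them stays open. Genes near the floor limit what the arrays can resolve, since both a small and a large fall end at about log2 3.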

Other observations

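The tests on HUVEC replicate 2, on cell cycle genes in NHLF and on interferon genes in NHEK were chosen only after the results were seen, and the tests over other splits of the samples before. Replicates of some types differed in whole groups of genes, seen in 1 array each and therefore without a test. In HepG2, 29 of 30 cell cycle genes were higher in replicate 2 than in replicate 1 (median 0.72) and 19 of 21 glycolysis and hypoxia genes were lower (median -0.92). IGFBP3 differed by -7.17, the gluconeogenic enzymes G6PC1 and PCK1 by -5.62 and -4.26, and TXNIP by -3.80. The 3' minus 5' value of ACTB was 3.36 in HepG2 replicate 1 and 2.62 in replicate 2, the widest pair of the 8 types. GM12878 moved the same way, by 0.37 for the cell cycle and by -0.52 for glycolysis and hypoxia, while its ACTB value went the other way, from 0.57 to 0.68. HSMM (0.35 and -0.15) and HMEC (0.27 and -0.13) moved that way by less, and NHEK only for the cell cycle (0.16 and -0.01). NHLF moved the opposite way (-1.71 and 0.24). HUVEC (0.045 and 0.038) and K562 (-0.045 and -0.029) hardly moved.

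In HSMM, 21 of 29 muscle genes were higher in replicate 2 (median 0.78), led by CKM by 3.21, MYH8 by 3.07, TNNI1 by 2.38 and myogenin (MYOG) by 2.23, while MYF5 and MYOD1 were at -0.46 and -0.69. In NHLF replicate 2, matrix genes were higher by a median of 0.54, CCN5 by 5.74, COL5A3 by 5.20 and COL4A1 by 4.86, while MMP1 was at -3.17, FOS at -3.40 and the channel TRPA1 at -4.35. Cholesterol genes were higher in HMEC replicate 2 for 14 of 14 (median 0.40). Faint signal of some of another type's brightest genes appeared in HMEC replicate 2 (ALB 4.99 against 3.13, IGL 5.17 against 3.14), HSMM replicate 1 (ALB 4.77 against 2.95, APOB 4.05 against 2.67) and NHLF replicate 2 (HBE1 at 5.72, NMU 5.17 against 2.96). The 20 brightest HepG2 genes differed (replicate 2 minus 1) by a median of 0.31 in HMEC and -0.46 in HSMM. In HSMM 9 of them lay under -0.5 and 3 over 0.5. Those of GM12878 differed by 0.06 in HMEC, and those of K562 by 0.07 in NHLF. In NHLF the 20 brightest HSMM genes differed more, by 0.43.

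Chance was tested by regrouping. The 8 epithelial and mesenchymal arrays can be split into 4 and 4 in 35 ways. Only 1 of these splits, the real one, gave as many called genes (1343, against 65 at most in the others). Each side of a split was given 1 mean here, unlike the main fit with 1 mean per cell type. Arrays of a type are not independent, though, and only 3 of these splits keep the arrays of each type together, the split at 65 among them, which is too few for a share under 0.05. Of the 56 splits of the 8 types into 3 and 5, only 1, the established lines, gave as many (178 against 14 at most). Though this share is under 0.05, 56 splits are too few to exclude chance. The types were also not interchangeable. The mean squared log2 difference of means was at least 2.02 (GM12878 and HUVEC) between a line and a culture. Between cultures it was at most 1.38 (HSMM and NHEK). The count therefore does not show that being established is what sets the 3 lines apart.

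The 20 brightest genes of HepG2 rose in HUVEC replicate 2 over replicate 1 by a median of 1.19, and those of the other types by 0.06 at most. The 5 brightest genes implied a share of HepG2 material of 0.506%, and the 9 of those ranked 21 to 40 that lay under log2 4 in replicate 1 a share of 0.0737%, a ratio of 6.87. Genes of like brightness in HepG2 rose unequally, SELENOP (12.04) by 1.46 and SERPINA3 (12.19) by 0.34. HepG2 material stays open, at a fixed share or with fainter additions lost near the floor, since additions near the floor are compressed and the rise of 1.19 is the observation that raised it. No biological explanation was tested.

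All 30 cell cycle genes were lower in NHLF replicate 2 than in replicate 1, 24 of them over 2-fold (median -1.71). Scaling of the arrays is argued against, as the lowest median of 10000 random lists of like expression was -0.42. The 3' minus 5' value of ACTB differed by -0.0695 between the NHLF arrays, against a median of 0.26 for the other pairs. For GAPDH it was 0.0032 in replicate 1 and -0.0191 in replicate 2. These controls showed little difference in RNA quality, but control transcripts cannot exclude one for the cell cycle genes. A difference in growth between the cultures may lie behind it and was not tested.

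Interferon response genes were higher in NHEK than in HMEC by a median of 2.42. Scaling of the arrays is argued against, as the highest median of 10000 random lists of like expression was 0.32. GM12878, the other type with high interferon genes, is argued against as a source of RNA, since the median of its 20 brightest genes differed by -0.15 between NHEK and HMEC. A difference of cell type, donor or culture could lie behind the pattern, and these were not tested.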
